A study of Mus musculus with 27 samples.

How the data were processed

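Microglia were sorted from tissue around the injection site of SPF, ABX and GF wild-type mice after collagenase-induced ICH (day 3 and day 7) or saline sham surgery (day 7), with 3 libraries in each of 9 groups, per the labels. Per the labels' protocols, libraries were made with a low-input kit for full-length cDNA (SMART-Seq v4) and sequenced in pairs of 150 bases on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR without a version, and the mm10 assembly. They do not state the annotation release, the strand setting or how mates were counted. The deposited table holds counts per gene for the 27 libraries, as whole numbers, per the file headers and the values. Symbols, coordinates and biotypes come from GENCODE M21, which gives a symbol to 52073 of 56691 gene identifiers, and the other 4618 hold 1.27% of counts.

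Groups were taken from the labels. Genes were kept by the filterByExpr rule of edgeR with the 9 groups, which left 17573 genes holding 99.9% of counts and set aside 39118. Library sizes were scaled by TMM, with factors from 0.476 to 1.31. All comparisons used 1 quasi-likelihood fit of edgeR 4.0.16 with robust estimates over the 9 group means, in R 4.3.3, and adjusted p-values by the Benjamini-Hochberg method at 0.05. The SE of a log2 fold change was taken from the quasi-likelihood F statistic. The common biological coefficient of variation was 1.54. In all, 19 comparisons were made: ICH day 3 and day 7 against sham in each condition, day 7 against day 3 in each, ABX and GF against SPF in sham, at day 3 and at day 7, and the interaction of each with the response at day 3 and day 7. Shams are labelled day 7, so comparisons of day 3 with sham also differ in day. Replicate numbers are shared between groups, but no label pairs them.

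A set of 14 functional lists and 11 lists of cell markers, fixed before the data were examined, was tested with camera of limma 3.58.1 at its preset correlation of 0.01 and with an estimated correlation, adjusted over the 25 lists of each comparison. The functional lists are homeostatic microglia, disease-associated microglia, interferon response, cytokines, alternative activation, heme and iron handling, antigen presentation, cell cycle, complement and phagocytosis, glycolysis, oxidative phosphorylation, short-chain fatty acid sensing and use, cholesterol and lipid metabolism, and immediate early and dissociation stress. The last is called immediate early genes below. The marker lists are neutrophil, monocyte, border-associated macrophage, T and NK cell, B cell, dendritic cell, astrocyte, oligodendrocyte, neuron, endothelial and erythroid. Counts "over the list alone" adjust p-values over the measured list members. Percentiles place a list's median among 10000 random lists matched on mean expression, a description added after the data were seen.

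Genes were named by a rule set before the data were examined. It takes the 5 largest rises and 5 largest falls past adjusted p 0.05 with a mean log2 CPM of at least 4 and no overlap between libraries of the 2 groups, an overlap that is allowed for interactions, and leaves out predicted genes and pseudogenes. It adds up to 4 members of each list with the smallest adjusted p, and always Ffar2, Ffar3, Hcar2, P2ry12, Tmem119, Apoe, Spp1, Hmox1, Il1b and Tnf. The levels of S100a8, Mmp9 and Csf3r were named after their values were seen. Log2 CPM used a prior count of 2. Where all libraries of a group had 0 counts, a lower bound of the fold change was computed with 3 counts per library in place of 0.

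Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors in the edgeR fit, no filter on low counts, a replicate block, and leaving out each library in turn. Alternatives added after the data were seen leave out the 7 libraries under 12000 detected genes, keep genes with a mean CPM of at least 100 (1570 genes), or add offsets for GC content. The GC offsets are a spline with 6 degrees of freedom per library, fitted on genes with a mean CPM of at least 100 and centred per library. A first version, fitted on genes of at least 10 CPM without centring, overcorrected and was replaced. The version used brings the Spearman correlation of log2 fold change with GC content over abundant genes near 0 in most comparisons, but still corrects too far in those with GF ICH day 7, where it is 0.233 against sham, 0.278 against day 3, 0.292 against SPF and 0.239 in the interaction. A call that ends there with the offsets may end through overcorrection. A first GC test on less abundant genes lower in GF than in SPF mice at day 7 compared their median GC content with that of other genes. It restated what had been seen and was replaced by the count kept with the offsets. Gene GC content was taken from the longest annotated transcript and covers 96.0% of tested genes.

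The fit was tested on simulated data for ICH day 3 against sham in SPF mice with 17573 genes, of which 200 were changed, 25 per fold size and direction. The edgeR fit found 0, 8, 16 and 25 of the genes raised 4-, 16-, 64- and 256-fold and 0, 0, 6 and 13 of those lowered as much, with 2 false calls. DESeq2 found 2, 14, 16 and 23 and 2, 12, 18 and 25, with 340 false calls, and limma voom 0, 8, 13 and 22 and 0, 0, 2 and 9, with 19. In this simulation changes of 4-fold were thus not found by edgeR. Its counts were drawn with the spread that edgeR had fitted to the data, with no GC trend and no loss of transcripts in single libraries. This may favour edgeR, so the false calls do not give error rates of these tools in the data. With a GC trend put on simulated GF ICH day 7 libraries and no change in any of 17573 genes, the edgeR fit gave 5601 false calls, and 3 with the GC offsets. This simulation used a much lower spread between libraries than the data have and a trend along a straight line. Its counts therefore do not carry over to the data, where the offsets correct too far with GF ICH day 7. Depth ran from 41664864 to 79090595 counts, and cut to equal depth the libraries still held 9061 to 18066 detected genes. Correlations between libraries with the same replicate number gave 0 of 15 comparisons with every pair above 0.1. Il10, Nos2 and Ffar3 had 0 counts in all libraries and were not tested. Some results for single genes are not reported here.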

Results

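To ask how the gut microbiota bears on microglia after intracerebral hemorrhage (ICH), RNA from microglia sorted from tissue around the hematoma was sequenced in 9 groups of 3 libraries. Specific pathogen-free (SPF) mice, mice given an antibiotic cocktail (ABX) and germ-free (GF) mice were each sampled at day 3 and day 7 after collagenase injection. Each condition has a sham group given saline, labelled day 7. The 27 libraries hold 41664864 to 79090595 counts each and 17573 genes were tested. Levels below are CPM (counts scaled by library size), as mean ± SD over n = 3 libraries per group, and log2 fold changes are given ± SE. For every gene described as higher or lower in 2 groups, all 3 libraries of one group lay above all 3 of the other unless stated.

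The number of genes detected per library ranged from 9185 to 18408 and differed by group. It was 9906 ± 997 in GF ICH day 7, 11801 ± 2135 in ABX ICH day 7 and 13553 ± 4280 in GF sham, against 15302 ± 1162 in SPF ICH day 7 and 15185 ± 1767 in SPF sham. Of the 27 libraries, 7 held under 12000 detected genes: all 3 of GF ICH day 7, replicates 1 and 2 of ABX ICH day 7, and replicates 1 and 2 of GF sham. Transcripts of high GC content were also less well represented in some groups. The median log2 level of the highest minus that of the lowest GC quintile of abundant genes, with each gene centred over all libraries, was −2.16 ± 0.67 in GF ICH day 7 and −0.78 ± 0.22 in ABX ICH day 7, against 0.28 ± 0.55 in SPF ICH day 7 and 1.28 ± 0.27 in GF ICH day 3. Mitochondrial transcripts made up 4.71 ± 1.51% of counts in GF ICH day 7, 2.96 ± 0.88% in ABX ICH day 7 and 1.57 ± 0.716% in SPF ICH day 7.

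**Figure D1:**
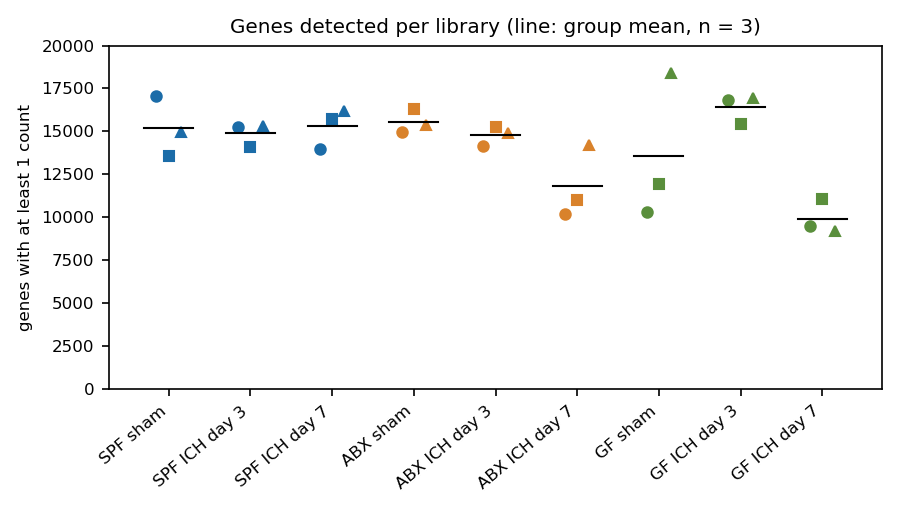
Genes detected per library by group, with 1 point per library and n = 3 libraries in each of the 9 groups.

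**Figure D2:**
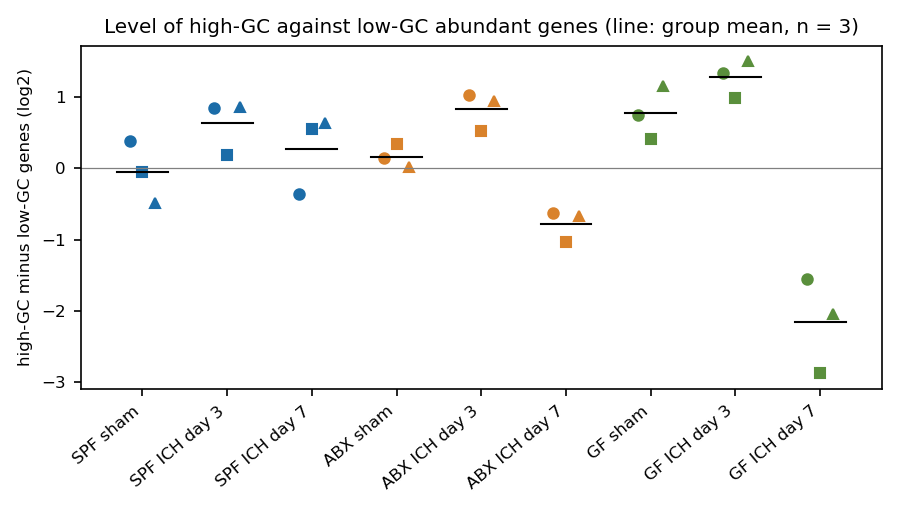
Level of the highest minus the lowest GC quintile of abundant genes in each library, in log2 units, with 1 point per library and n = 3 per group.

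How do microglia of SPF mice respond by day 3? Spp1, which encodes osteopontin, rose 5.50 ± 0.66 log2 units, from 77.7 ± 40.5 CPM in sham to 3506 ± 1024 CPM after ICH (edgeR adjusted p = 0.000276). Apoe, the lipid carrier apolipoprotein E, rose 3.92 ± 0.52, from 437 ± 241 to 6597 ± 1058 CPM (edgeR adjusted p = 0.000384). Ftl1, a ferritin light chain that stores iron, rose 3.17 ± 0.40 to 25826 ± 2995 CPM, and the inhibitory receptor gene Lilrb4a rose 6.29 ± 0.84 (edgeR adjusted p = 0.000384 for each). Cst3, the cysteine protease inhibitor cystatin C that is abundant in resting microglia, fell 1.79 ± 0.26 below sham, from 29179 ± 2710 to 8451 ± 1105 CPM (edgeR adjusted p = 0.00155). The purinergic receptor gene P2ry12, a marker of resting microglia, did not pass, at −1.76 ± 0.36 and 2410 ± 636 against 8185 ± 2098 CPM (edgeR adjusted p = 0.0567).

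Disease-associated microglia genes moved up as a group at day 3 in SPF mice. Of 21 measured, 6 rose and none fell over all genes, and 14 rose and 1 fell when adjusted over the list alone (limma camera adjusted p = 1.05e-28 and 0.000183 with an estimated correlation). Cell cycle genes had the largest median, 5.29, with 1 of 22 rising, Stmn1, a regulator of microtubules, and 12 over the list alone (limma camera adjusted p = 6.71e-29, and adjusted p = 0.000367 with an estimated correlation). The interferon list had a median of 2.26 with 0 of 22 passing and 2 over the list alone (limma camera adjusted p = 5.69e-13, and 0.0096 with an estimated correlation). Antigen presentation had 1 of 18 rising, H2-Ab1, a class II chain, and 7 over the list alone, and glycolysis 0 of 18 and 6 (limma camera adjusted p = 6.73e-06 and 1.39e-06, and adjusted p = 0.00106 and 0.00198 with an estimated correlation). Cholesterol and lipid metabolism had 1 of 20 rising, Apoe, which the disease-associated list also holds, and 3 over the list alone (limma camera adjusted p = 0.000139, and adjusted p = 0.0439 with an estimated correlation).

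Calls of other groups at day 3 in SPF mice were lost with an estimated correlation. Homeostatic microglia genes had a median of −0.85, with 0 of 18 passing and 6 lower over the list alone (limma camera adjusted p = 1.09e-07, and adjusted p = 0.0548 with an estimated correlation). Heme and iron handling had 2 of 20 rising, Ftl1 and Fth1, the ferritin chains, and 3 over the list alone (limma camera adjusted p = 0.000625, and adjusted p = 0.0714 with an estimated correlation). Hmox1, the heme oxygenase of the same list, stood at 1392 ± 457 against 40.04 ± 8.26 CPM and did not pass in edgeR (5.12, edgeR adjusted p = 0.266), although it passed in DESeq2 (adjusted p = 0.000325) and limma voom (adjusted p = 0.00266). Alternative activation, with 0 of 13 passing, and complement and phagocytosis, with 0 of 19, had limma camera adjusted p = 0.00752 and 0.0149, and adjusted p = 0.0714 and 0.197 with an estimated correlation. The first call ended without SPF sham replicate 3 (limma camera adjusted p = 0.0771) and the second without SPF ICH day 3 replicate 1 (0.0658), SPF sham replicate 1 (0.0516) or replicate 3 (0.0508). Oxidative phosphorylation, with 0 of 21 passing, had a median of 0.31 (limma camera adjusted p = 0.154). Cytokines, with 0 of 18, and immediate early genes, a list that also covers dissociation stress, with 0 of 17, had limma camera adjusted p = 0.033 and 0.0154, and adjusted p = 0.158 and 0.182 with an estimated correlation. Without SPF sham replicate 1 the limma camera adjusted p of cytokines was 0.185, and without replicate 2 that of immediate early genes was 0.787.

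Markers of other cells were tested as lists too. Monocyte and border-associated macrophage lists, which share F13a1, had medians of 4.25 and 4.79 at day 3 in SPF mice with 0 of 11 and 0 of 9 genes passing (limma camera adjusted p = 0.000108 and 1.69e-05, and adjusted p = 0.0533 and 0.0208 with an estimated correlation). Dendritic cell markers had a median of 2.40 with 0 of 6 passing (limma camera adjusted p = 0.00918, and 0.0514 without SPF sham replicate 1). Medians were below 0 for neutrophil (−2.92), astrocyte (−3.05), oligodendrocyte (−3.49) and neuron (−4.59) markers, with no gene passing (limma camera adjusted p = 0.0243, 0.0205, 0.0566 and 0.0106, and adjusted p = 0.178, 0.0875, 0.296 and 0.117 with an estimated correlation). Without SPF sham replicate 2 the limma camera adjusted p of neutrophil, astrocyte and neuron markers was 0.404, 0.678 and 0.339. T and NK cell (−0.45), B cell (−0.04), endothelial (−0.66) and erythroid (0.71) medians did not pass (limma camera adjusted p = 0.978, 0.978, 0.431 and 0.735).

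In edgeR 16 genes rose and 2 fell at day 3 in SPF mice, with 1276 at unadjusted p below 0.05. DESeq2 called 954 and limma voom 529. Leaving out SPF sham replicate 1 left 7 genes, sham replicate 2 left 8 and ICH day 3 replicate 1 left 11. Of 12 named calls 5 (Spp1, Apoe, Lilrb4a, Ftl1 and Cst3) held whichever library was left out. Fth1 was not called without SPF sham replicate 1 (edgeR adjusted p = 0.0684), nor Stmn1 and H2-Ab1 without that library (edgeR adjusted p = 0.353 and 0.259) or other single ones. Calls of Stmn1 and H2-Ab1 also ended with the GC offsets (edgeR adjusted p = 0.148 and 0.156). With DESeq2 size factors the scaling left 9 genes, without Cst3 (edgeR adjusted p = 0.0548), and the median log2 fold change moved from −0.07 to −0.14. In limma voom Spp1 and Apoe were not called (limma adjusted p = 0.589 and 0.535). The edgeR fit shares its estimate of spread over all 27 libraries. At day 3 and day 7 more genes passed in SPF mice without the 7 libraries under 12000 detected genes, none of them SPF. Counts of calls thus do not rank the conditions by size of response.

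At day 7 in SPF mice Spp1 reached 16881 ± 11494 CPM (7.76 ± 0.73, edgeR adjusted p = 1.6e-06) and Apoe 29935 ± 10460 CPM (6.10 ± 0.58, edgeR adjusted p = 1.6e-06). Fabp5, a fatty acid binding protein, rose 7.71 ± 1.10 (edgeR adjusted p = 0.0013). Cst7, the protease inhibitor cystatin F, rose 5.89 ± 0.85 to 369 ± 147 CPM (edgeR adjusted p = 0.00138). These 4 calls held whichever library was left out. P2ry12 (−0.99 ± 0.36) and the microglial marker Tmem119 (−0.52 ± 0.67) did not pass (edgeR adjusted p = 0.897 and 1).

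By number of calls disease-associated genes again led the lists at day 7, with 8 of 21 rising and none falling, and 15 over the list alone (limma camera adjusted p = 1.14e-52, and adjusted p = 3.43e-06 with an estimated correlation). The interferon list had a median of 3.43, with 1 of 22 rising, Ifitm3, a restriction factor, and 7 over the list alone (limma camera adjusted p = 2e-30, and adjusted p = 0.000154 with an estimated correlation). Antigen presentation had 1 of 18 and 8 over the list alone, and cell cycle 0 of 22 and 8, with a median of 3.28 (limma camera adjusted p = 1.18e-10 and 2.41e-17, and adjusted p = 3.65e-05 and 0.00338 with an estimated correlation). Homeostatic genes had a median of −0.59 with 0 of 18 passing (limma camera adjusted p = 1e-05, and adjusted p = 0.0911 with an estimated correlation). Neuron markers had a median of −6.82, with 0 of 6 passing and 3 lower over the list alone (limma camera adjusted p = 0.000154, and adjusted p = 0.0304 with an estimated correlation). Monocyte, border-associated macrophage and dendritic cell markers had medians of 2.34, 4.62 and 4.79 at day 7 in SPF mice, with 0 of 11, 0 of 9 and 0 of 6 passing and 3, 2 and 1 over the list alone (limma camera adjusted p = 6.31e-06, 2.55e-06 and 9.48e-05, and adjusted p = 0.0265, 0.0102 and 0.00472 with an estimated correlation). The heme and iron list had a median of 0.18, a mean of −0.29 and an upward test that did not pass (limma camera adjusted p = 0.379).

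In edgeR 14 genes rose and 0 fell at day 7 in SPF mice, with 880 at unadjusted p below 0.05, against 709 in DESeq2 and 148 in limma voom. Without SPF sham replicates 1, 2 or 3 the count was 5, 6 or 7, and without SPF ICH day 7 replicate 1 or 3 it was 8. Ifitm3 was not called without any of these 5 libraries in turn, with edgeR adjusted p = 0.245 at the most, without SPF sham replicate 3. Spp1 and Apoe were not called by limma voom (limma adjusted p = 0.607 and 0.42).

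**Figure D3:**
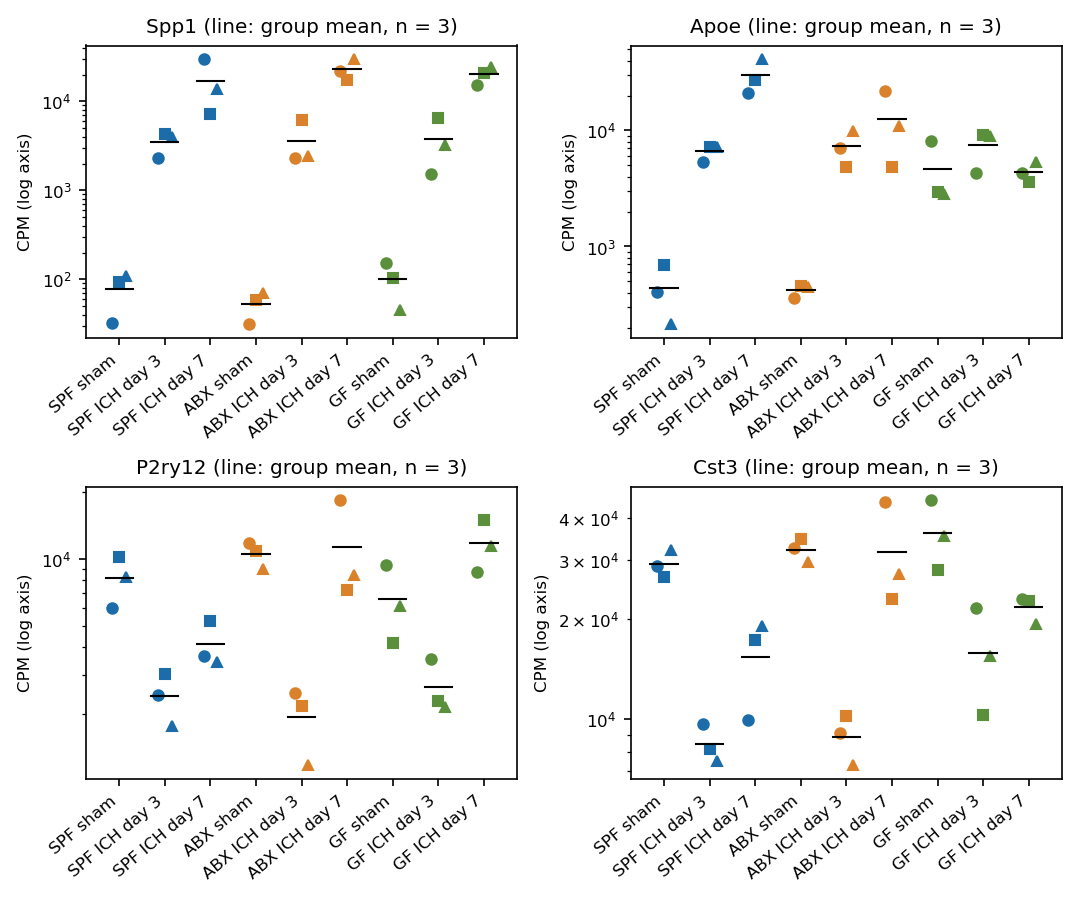
CPM of Spp1, Apoe, P2ry12 and Cst3 in each library, with 1 point per library and n = 3 per group.

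Does the response in ABX mice involve these genes? At day 3 Spp1 rose 6.09 ± 0.68, from 53.2 ± 19.97 to 3628 ± 2189 CPM (edgeR adjusted p = 7.01e-05). Apoe rose 4.11 ± 0.53, from 422 ± 56.9 to 7279 ± 2511 CPM (edgeR adjusted p = 0.000437). The ferritin genes Ftl1 and Fth1 rose 2.67 ± 0.40 and 2.26 ± 0.33 (edgeR adjusted p = 0.00197 for each). P2ry12 fell by 2.44 ± 0.37 log2 units, from 10547 ± 1427 to 1938.5 ± 682 CPM (edgeR adjusted p = 0.00206). Cst3 fell by 1.86 ± 0.26 (edgeR adjusted p = 0.00171). These 6 of 15 named calls held whichever library was left out. SPF and ABX mice shared 13 genes higher at day 3, where 0.0164 would be shared by chance, and 1 lower, Cst3. The 13 count Ftl1, Ftl1-ps1 and Ftl2-ps apart. The chance value takes calls as independent draws from all tested genes, although 15 of 16 and 16 of 18 higher calls had a mean CPM of at least 100. It is thus too low. Both comparisons also share a GC trend (Spearman 0.310 in SPF and 0.328 in ABX mice over abundant genes), from which a larger overlap may arise. With the GC offsets 11 of the 15 and 13 of the 16 abundant higher calls stayed.

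Disease-associated genes at day 3 in ABX mice had 5 of 21 rising and 14 rising and 1 falling over the list alone (limma camera adjusted p = 5.56e-23, and adjusted p = 0.000615 with an estimated correlation). Homeostatic genes had 3 of 18 falling, P2ry12 and the purinergic and lipid receptor genes P2ry13 and Gpr34, and 5 over the list alone (limma camera adjusted p = 2.1e-06, and adjusted p = 0.0822 with an estimated correlation). Cell cycle genes had a median of 4.17 with 1 of 22 rising and 5 over the list alone, and interferon genes 2.17 with 0 of 22 and 2 (limma camera adjusted p = 3.13e-24 and 2.06e-10, and adjusted p = 0.00115 and 0.0206 with an estimated correlation). Antigen presentation had 3 of 18 rising, the class II chains H2-Ab1 and H2-Eb1 and the invariant chain Cd74, and 6 over the list alone (limma camera adjusted p = 0.00011, and adjusted p = 0.00308 with an estimated correlation). Monocyte, border-associated macrophage and dendritic cell markers had medians of 2.90, 4.20 and 3.91 beside these, with no gene passing (limma camera adjusted p = 0.00011, 2.13e-05 and 0.00729, and adjusted p = 0.0605, 0.0285 and 0.0431 with an estimated correlation). The dendritic cell call ended without ABX sham replicate 2 (limma camera adjusted p = 0.0649). In edgeR 18 genes rose and 4 fell, with 1453 at unadjusted p below 0.05, against 1086 in DESeq2 and 868 in limma voom, which did not call Spp1 or Apoe (limma adjusted p = 0.414 and 0.307). The count was 7 without ABX sham replicate 1, 12 without sham replicate 2, 10 without sham replicate 3, and 12 or 14 without ICH day 3 replicate 2 or 3. It was 14 with DESeq2 size factors. P2ry13, Gpr34, H2-Ab1, H2-Eb1 and Cd74 were not called without ABX sham replicate 1 (edgeR adjusted p = 0.0965, 0.0725, 0.0915, 0.455 and 0.374). Calls of Gpr34, H2-Eb1 and Cd74 also ended with the GC offsets (edgeR adjusted p = 0.0603, 0.0712 and 0.0661), with H2-Eb1 at 5.41 in place of 5.72 and Cd74 at 3.84 in place of 4.45.

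At day 7 in ABX mice Spp1 rose 8.77 ± 0.76 to 23161 ± 6402 CPM (edgeR adjusted p = 5.64e-07) and Apoe 4.89 ± 0.55 to 12521 ± 8591 CPM (edgeR adjusted p = 2.47e-05). B2m, the light chain of MHC class I, rose 2.25 ± 0.28, from 3048 ± 246 to 14515 ± 1759 CPM (edgeR adjusted p = 0.000135). H2-Ab1 rose 6.57 ± 1.01 (edgeR adjusted p = 0.000962). The chemokine gene Ccl12 rose 4.36 ± 0.63 (edgeR adjusted p = 0.000534). Slc35b2, a Golgi sulfate donor transporter, fell by 4.94 ± 0.89 log2 units, from 184 ± 36.0 to 6.02 ± 5.21 CPM (edgeR adjusted p = 0.0055). P2ry12 did not pass at day 7 (0.11 ± 0.35, edgeR adjusted p = 0.872).

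Of 21 disease-associated genes 12 rose at day 7 in ABX mice, and 15 over the list alone (limma camera adjusted p = 1.06e-28, and adjusted p = 0.000163 with an estimated correlation). Interferon genes had a median of 4.43 with 4 of 22 rising and 13 over the list alone, and antigen presentation 5 of 18, with 8 rising and 2 falling over the list alone (limma camera adjusted p = 1.45e-15 and 7.2e-07, and adjusted p = 0.00575 and 0.000561 with an estimated correlation). The antigen presentation median of 0.92 lay at percentile 63.1 of expression-matched lists, whose median was 0.81. Monocyte and border-associated macrophage markers had medians of 4.96 and 4.21 beside these, with no gene passing and 4 of 11 and 0 of 9 over the list alone (limma camera adjusted p = 1.52e-05 and 0.0182, and adjusted p = 0.0509 and 0.24 with an estimated correlation). The second call ended without ABX ICH day 7 replicate 2 or 3 (limma camera adjusted p = 0.0514 and 0.257). Cytokines had 3 of 18 rising, Ccl12, Ccl4 and Ccl3, and 1 falling, the adhesion molecule gene Icam1 (limma camera adjusted p = 0.00117, and adjusted p = 0.049 with an estimated correlation). Oxidative phosphorylation had a median of 1.17 with 0 of 21 passing and 1 over the list alone (limma camera adjusted p = 3.71e-08, and adjusted p = 0.0509 with an estimated correlation), at percentile 70.3 of expression-matched lists, whose median was 1.03. Immediate early genes had a median of −1.97, with 1 of 17 falling, Fosb, and 5 over the list alone (limma camera adjusted p = 0.00395, and adjusted p = 0.148 with an estimated correlation). The cholesterol list had a median of −1.09 and a mean of −0.47 but an upward test (limma camera adjusted p = 0.0333, and adjusted p = 0.259 with an estimated correlation), which ended without ABX sham replicate 3 (limma camera adjusted p = 0.114).

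In edgeR 129 genes rose and 37 fell at day 7 in ABX mice, with 3776 at unadjusted p below 0.05, against 4890 in DESeq2 and 581 in limma voom. The median GC content was 46.3% in higher, 51.8% in lower and 49.0% in other genes. The count was 29 without ABX sham replicate 1 or 3, 40 without sham replicate 2, 97 without ICH day 7 replicate 1 and 603 without ICH day 7 replicate 3, the library of that group with the most detected genes. With DESeq2 size factors 90 genes passed, the median log2 fold change moved from −0.79 to −1.19 and the share of calls that were higher went from 77.7% to 57.8%. A replicate block gave 105 calls and no filter on low counts 56. In limma voom Spp1, Apoe and Slc35b2 were not called (limma adjusted p = 0.169, 0.278 and 0.0709). Calls of Ccl3, Ccl4, Icam1 and Fosb ended without ABX sham replicate 1 (edgeR adjusted p = 0.177, 0.0857, 0.0639 and 0.121), and without other single libraries. That of Fosb also ended with the GC offsets (edgeR adjusted p = 0.0692).

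What changes in GF mice? At day 3 1 gene passed, Spp1, which rose 5.22 ± 0.65 from 101 ± 53.6 to 3755 ± 2504 CPM (edgeR adjusted p = 0.000551). Apoe, at 7454 ± 2755 against 4629 ± 2997 CPM, did not pass (0.69 ± 0.47, edgeR adjusted p = 0.823), nor did P2ry12 (−1.31 ± 0.36, edgeR adjusted p = 0.57) or Hmox1 (5.19, edgeR adjusted p = 0.435, and adjusted p = 0.000711 in DESeq2). Disease-associated genes had a median of 1.11, with 1 of 21 rising and 8 over the list alone, and interferon genes 3.14 with 0 of 22 and 3 (limma camera adjusted p = 1.78e-08 and 4.62e-10, and adjusted p = 0.0375 for each with an estimated correlation). Monocyte markers had a median of 3.78 beside these, with 0 of 11 passing and 4 over the list alone (limma camera adjusted p = 0.000495, and adjusted p = 0.139 with an estimated correlation). That call ended without GF sham replicate 3 (limma camera adjusted p = 0.189). Homeostatic genes had a median of −0.92, with 0 of 18 passing and 5 lower over the list alone, and cell cycle genes 3.04 with 0 of 22 (limma camera adjusted p = 2.52e-09 and 7.95e-07, and adjusted p = 0.0843 for each with an estimated correlation). In edgeR 929 genes had unadjusted p below 0.05, and DESeq2 called 720 and limma voom 0 (limma adjusted p of Spp1 = 0.873). Leaving out GF sham replicate 3, the sham library with the most detected genes, gave 54 genes. Without the 7 libraries under 12000 detected genes Spp1 was not called (edgeR adjusted p = 0.531).

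At day 7 in GF mice more genes fell than rose, an excess found among less abundant genes alone in the fit without GC offsets. Spp1 rose 7.64 ± 0.73 to 20070.5 ± 4611 CPM (edgeR adjusted p = 2.42e-06). Clec7a, a receptor for fungal glucans found on activated microglia, rose 6.95 ± 0.80, from 13.8 ± 14.2 to 1710 ± 508 CPM (edgeR adjusted p = 1.75e-05). Ccr2, a chemokine receptor of monocytes, rose 8.90 ± 1.80, from 0.880 ± 0.427 to 419 ± 325 CPM (edgeR adjusted p = 0.00252). The cytokine gene Il1b rose 8.35 ± 2.28 (edgeR adjusted p = 0.0164). Csf1r, the receptor on which microglia depend for survival, fell by 5.94 ± 1.00 log2 units, from 8030 ± 7195 to 131 ± 114 CPM, and the fractalkine receptor gene Cx3cr1 fell by 4.04 ± 0.50, from 8419 ± 4016 to 511 ± 313 CPM (edgeR adjusted p = 0.000569 and 3.62e-05). Tmem119 fell by 3.51 ± 0.74, from 7252 ± 2575 to 635 ± 296 CPM, while Gpr34 rose 1.92 ± 0.34, from 2220 ± 674 to 8395 ± 1357 CPM (edgeR adjusted p = 0.00323 and 0.000896). C1qb, a chain of complement C1q, fell by 2.26 ± 0.36 (edgeR adjusted p = 0.000358). P2ry12 (0.83 ± 0.36) and Apoe (−0.07 ± 0.46, 4424 ± 865 against 4629 ± 2997 CPM) did not pass (edgeR adjusted p = 0.112 and 0.981).

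Disease-associated genes had 11 of 21 rising and 2 falling at day 7 in GF mice, and 11 and 4 over the list alone (limma camera adjusted p = 1.55e-11, and adjusted p = 0.0158 with an estimated correlation). Immediate early genes had 8 of 17 falling and 1 rising, and 11 and 1 over the list alone, with a median of −4.59, led by Dusp1, Egr1 and Fos at −8.93, −9.23 and −8.47 (limma camera adjusted p = 4.38e-05, and adjusted p = 0.0806 with an estimated correlation). Glycolysis had 6 of 18 falling and 9 over the list alone, with a median of −2.71 and Aldoa at −3.03 ± 0.60 (limma camera adjusted p = 0.0167, and adjusted p = 0.121 with an estimated correlation, and 0.106 without GF sham replicate 1). Homeostatic genes had 1 of 18 rising, Gpr34, and 6 falling, with 2 and 9 over the list alone (limma camera adjusted p = 0.0649). Interferon genes had 5 of 22 rising and 1 falling, and 7 and 1 over the list alone (limma camera adjusted p = 4.73e-05, and adjusted p = 0.121 with an estimated correlation). Complement had 3 of 19 rising and 4 falling, and 3 and 8 over the list alone (limma camera adjusted p = 0.942). Oxidative phosphorylation had 0 of 21 rising and 4 falling (limma camera adjusted p = 0.153). Monocyte markers had 5 of 11 rising and 1 falling and neutrophil markers 1 of 10 rising, Cxcr2, at 79.6 CPM in the mean against 0 counts in sham (limma camera adjusted p = 2.36e-05 and 0.009, and adjusted p = 0.0806 and 0.128 with an estimated correlation). Cxcr2 was above sham in 2 of 3 libraries and at least 1273-fold higher in the mean (edgeR adjusted p = 0.0383, 0.0938 without GF sham replicate 3 and 0.0523 with the GC offsets). The neutrophil call ended without GF sham replicate 3 (limma camera adjusted p = 0.0525). Antigen presentation had 5 of 18 rising and 1 falling, a median of −0.45, a mean of 0.28 and an upward test (limma camera adjusted p = 0.0209, and adjusted p = 0.106 with an estimated correlation), which ended without GF ICH day 7 replicate 1 (limma camera adjusted p = 0.15).

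In edgeR 298 genes rose and 2238 fell at day 7 in GF mice, with 5746 at unadjusted p below 0.05, against 6932 in DESeq2 and 1197 in limma voom. Among genes with a mean CPM of at least 100 the calls were 196 higher and 190 lower, against 102 and 2048 among the rest. With the GC offsets 59 of those 196 and 85 of those 190 stayed called. Of the lower genes, 564 had 0 counts in all 3 GF ICH day 7 libraries. Median GC content was 43.2% in higher, 52.0% in lower and 48.5% in other genes, and over 1563 abundant genes GC content and log2 fold change had a Spearman correlation of −0.546. With GC offsets that correlation turned to 0.233, so the offsets correct too far here, and 1683 of the 2536 calls remained. Those of Gpr34, C1qb, Tmem119 and Aldoa ended with them (edgeR adjusted p = 1, 0.709, 0.154 and 0.684), and the glycolysis list did not pass (limma camera adjusted p = 0.973). Apoe, which did not pass otherwise, was 2.41 ± 0.39 higher with the offsets and passed (edgeR adjusted p = 0.000715). The median log2 fold change was −2.10, and −2.63 with DESeq2 size factors. Without GF ICH day 7 replicate 3 the count was 1648. In limma voom Spp1, Ccr2, Il1b, Csf1r, Tmem119, C1qb and Aldoa were not called (limma adjusted p = 0.509, 0.0604, 0.0632, 0.108, 0.108, 0.295 and 0.0535), nor were Dusp1, Egr1 and Fos (limma adjusted p = 0.102, 0.076 and 0.182).

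**Figure D4:**
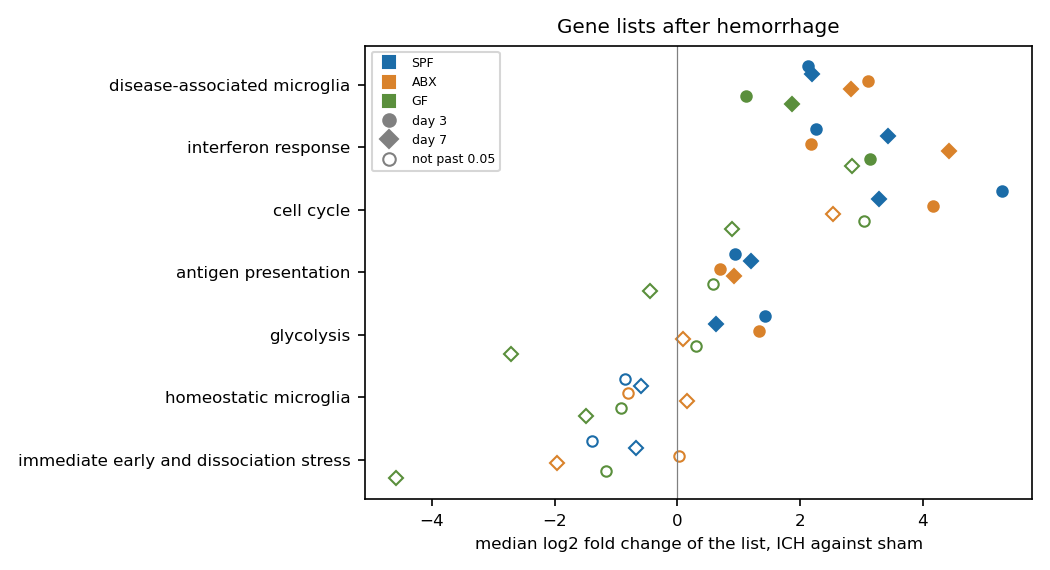
Median log2 fold change of selected functional gene lists after ICH in SPF, ABX and GF mice, with n = 3 libraries per group. Filled symbols passed an adjusted p of 0.05 in limma camera with an estimated correlation.

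Does the response change between day 3 and day 7? In SPF mice 0 genes passed in edgeR, with 719 at unadjusted p below 0.05, 662 calls in DESeq2 and 88 in limma voom. Spp1 and Apoe were 2.27 ± 0.57 and 2.18 ± 0.48 higher at day 7 without passing (edgeR adjusted p = 0.971 for each), and Hmox1 stood at −2.90 ± 1.17 (edgeR adjusted p = 0.971). Cell cycle genes had a median of −1.40, with 0 of 22 passing, and disease-associated genes 0.63 with 0 of 21 and 3 over the list alone (limma camera adjusted p = 8.96e-09 and 3.05e-05, and adjusted p = 0.14 and 0.201 with an estimated correlation).

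In ABX mice P2ry12 rose 2.55 ± 0.37 from day 3 to day 7, from 1938.5 ± 682 to 11380.5 ± 6182 CPM (edgeR adjusted p = 0.00104). Gpr34 rose 2.96 ± 0.36 and B2m 2.73 ± 0.29 (edgeR adjusted p = 0.000138 and 2.15e-05), calls that held whichever library was left out. Homeostatic genes had 5 of 18 rising, and 6 over the list alone, and disease-associated genes 5 of 21 and 9 (limma camera adjusted p = 3.99e-05 and 1.97e-07, and adjusted p = 0.232 and 0.104 with an estimated correlation). Their medians of 0.22 and 1.07 lay at percentiles 0.24 and 72.3 of expression-matched lists, whose medians were 1.05 and 0.90. The homeostatic call ended without ABX ICH day 7 replicate 1 (limma camera adjusted p = 0.0588). In edgeR 99 genes rose and 29 fell, with 3663 at unadjusted p below 0.05, against 4817 in DESeq2 and 349 in limma voom. The count was 29, 36 or 70 without ABX ICH day 3 replicate 3, 1 or 2, 68 without day 7 replicate 1 and 637 without day 7 replicate 3. With DESeq2 size factors it was 64, and the share of calls that were higher went from 77.3% to 56.25%. Median GC content was 43.1% in higher and 52.8% in lower genes, with a Spearman correlation of −0.513 over abundant genes. The GC offsets, which bring it to 0.0912, kept 63 of the 128 calls, with Gpr34 at 1.93 and P2ry12 at 1.71 (edgeR adjusted p = 0.0129 and 0.0352).

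In GF mice Hmox1 fell by 6.05 ± 1.36 log2 units from day 3 to day 7, from 1296 ± 572 to 19.5 ± 31.9 CPM, and Rac2, a small GTPase of leukocytes, fell by 7.32 ± 0.87 (edgeR adjusted p = 0.00568 and 3.41e-05). Mki67, a proliferation marker, fell by 9.67 log2 units (edgeR adjusted p = 0.0063), while Clec7a rose 4.60 ± 0.72 (edgeR adjusted p = 0.000413). P2ry12 rose 2.14 ± 0.37 (edgeR adjusted p = 0.000909), but was at −0.15 with the GC offsets (edgeR adjusted p = 0.83), which turn the Spearman correlation with GC from −0.731 to 0.278. Cell cycle genes had 1 of 22 rising and 7 falling, glycolysis 0 of 18 rising and 8 falling, and heme and iron handling 0 of 20 and 5 (limma camera adjusted p = 0.239, 0.00343 and 0.32), the second at adjusted p = 0.201 with an estimated correlation. In edgeR 322 genes rose and 2358 fell, with 6178 at unadjusted p below 0.05, against 6852 in DESeq2 and 5014 in limma voom. Among abundant genes 271 were higher and 135 lower, and among the rest 51 and 2223. With the GC offsets, which correct too far here, 40 of those 271 and 56 of those 135 stayed called. Without GF ICH day 7 replicate 3 the count was 1594. With the GC offsets it was 1757, of which 1508 were shared. Median GC was 42.1% in higher and 51.8% in lower genes, and 709 of the lower genes had 0 counts in all 3 day 7 libraries.

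Do the conditions differ without hemorrhage? Between ABX and SPF sham 0 genes passed in edgeR, with 712 at unadjusted p below 0.05, 576 calls in DESeq2 and 108 in limma voom. Apoe, Spp1 and P2ry12 stood at −0.05 ± 0.46, −0.55 and 0.37 (edgeR adjusted p = 1 for each). No list passed (lowest limma camera adjusted p = 0.0902). In GF sham 1 gene passed, Apoe, 3.41 ± 0.51 higher than in SPF sham, at 4629 ± 2997 against 437 ± 241 CPM (edgeR adjusted p = 0.0115). That call was not made in limma voom (adjusted p = 0.893) with DESeq2 size factors (edgeR adjusted p = 0.0866) or with the GC offsets (edgeR adjusted p = 0.262). It also ended without GF sham replicate 1, SPF sham replicate 1 or SPF sham replicate 3 (edgeR adjusted p = 0.13, 0.245 and 0.235), while 35 genes passed without GF sham replicate 3. Disease-associated genes had a median of 0.67 in GF sham, with 1 of 21 higher and 6 over the list alone, and complement 1.00 with 0 of 19 and 4 (limma camera adjusted p = 2.69e-05 for each, and adjusted p = 0.0987 for each with an estimated correlation), at percentiles 86.97 and 99.2 of expression-matched lists. The complement call ended without GF sham replicate 1 (limma camera adjusted p = 0.0545). Erythroid markers had a median of 3.43, with 0 of 5 passing and 3 over the list alone, and T and NK cell markers −1.51 with 0 of 11 (limma camera adjusted p = 0.000124 and 0.0218, and adjusted p = 0.118 and 0.509 with an estimated correlation). The T and NK cell call ended without GF sham replicate 1 or 3 or SPF sham replicate 1 (limma camera adjusted p = 0.379, 0.143 and 0.251). In GF against SPF sham 1093 genes had unadjusted p below 0.05 in edgeR, and DESeq2 called 876 and limma voom 0.

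Do the conditions differ at day 3? Between ABX and SPF mice 0 genes passed in edgeR, with 860 at unadjusted p below 0.05, 761 in DESeq2 and 38 in limma voom. Spp1, Apoe and P2ry12 stood at 0.05 ± 0.54, 0.14 and −0.31 (edgeR adjusted p = 1 for each). Between GF and SPF mice 0 genes passed in edgeR, with 608 at unadjusted p below 0.05, 571 in DESeq2 and 260 in limma voom. Spp1, Apoe and P2ry12 stood at 0.10 ± 0.54, 0.18 ± 0.46 and 0.14 (edgeR adjusted p = 1 for each). Neutrophil markers had a median of 6.70 in GF over SPF mice, with 0 of 10 passing even over the list alone (limma camera adjusted p = 4.3e-08, and adjusted p = 0.0155 with an estimated correlation). S100a8, a calcium-binding protein of granulocytes, stood at 54.7 ± 33.2 against 2.91 ± 3.34 CPM, and the gelatinase gene Mmp9 at 18.5 ± 5.82 CPM against 0 counts. Of the 10 list genes, Csf3r, a cytokine receptor gene at 84.6 ± 48.0 CPM in SPF sham, is also expressed by microglia. Cell cycle genes had a median of −0.86 with 0 of 22 passing (limma camera adjusted p = 0.000175, and adjusted p = 0.55 with an estimated correlation).

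Do they differ at day 7? In ABX over SPF mice 13 genes were higher and 2 lower, among them Gpr34 at 1.85 ± 0.34, the translocon gene Tram1 at 2.37 ± 0.45 and Glb1, a lysosomal galactosidase, at −5.11 ± 0.95 (edgeR adjusted p = 0.0403 for each). None of the 6 named calls held whichever library was left out: 0 genes passed without ABX ICH day 7 replicate 1 or SPF ICH day 7 replicate 2 or 3, 1 without SPF ICH day 7 replicate 1, and 388 without ABX ICH day 7 replicate 3. With DESeq2 size factors, no filter on low counts or a replicate block 0 passed, and 1 with the GC offsets. In edgeR 3415 genes had unadjusted p below 0.05, and DESeq2 called 4466 and limma voom 258. Oxidative phosphorylation moved up, with 0 of 21 passing and 6 over the list alone (limma camera adjusted p = 9.31e-10, and adjusted p = 0.128 with an estimated correlation), at percentile 92.8 of expression-matched lists. In this comparison the Spearman correlation with GC over abundant genes was −0.385. Mitochondrial transcripts took 2.96% of counts in ABX and 1.57% in SPF ICH day 7. T and NK cell markers had a median of 2.40, with 0 of 11 passing (limma camera adjusted p = 0.000456, and adjusted p = 0.46 with an estimated correlation). P2ry12 (1.47 ± 0.36) and Apoe (−1.26 ± 0.47) did not pass (edgeR adjusted p = 0.0943 and 0.213).

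In GF compared with SPF mice at day 7, Apoe was lower, with a log2 fold change of −2.76 ± 0.49, at 4424 ± 865 against 29935 ± 10460 CPM (edgeR adjusted p = 0.00197). It was −1.34 with the GC offsets (edgeR adjusted p = 0.029). Cx3cr1 was at −2.69 ± 0.47 and Rac2 at −6.69 ± 0.85 (edgeR adjusted p = 0.0016 and 8.87e-05). Tlr13, a sensor of bacterial ribosomal RNA, was higher by 3.26 ± 0.55 (edgeR adjusted p = 0.00144). Gpr34 and P2ry12 were higher by 2.14 ± 0.34 and 1.51 ± 0.36 (edgeR adjusted p = 0.00105 and 0.0104), calls that ended with the GC offsets (edgeR adjusted p = 0.65 and 0.572). P2ry12 was also not called in DESeq2 (adjusted p = 0.0626) or with DESeq2 size factors (edgeR adjusted p = 0.0575). Retnlg, a granulocyte resistin-like gene, stood at 538 ± 370 against 0.763 ± 0.383 CPM and passed (9.46 ± 3.12, edgeR adjusted p = 0.0474), but not when any 1 of the 6 libraries was left out. Neutrophil markers had a median of 7.60 with 1 of 10 higher and 6 over the list alone, and monocyte markers 2.81 with 1 of 11, Ccr2 (limma camera adjusted p = 0.000118 and 0.007, and adjusted p = 0.155 and 0.324 with an estimated correlation). Ccr2 was not called without GF ICH day 7 replicate 1 or SPF ICH day 7 replicate 2 or 3 (edgeR adjusted p = 0.0914, 0.105 and 0.104). Calls of Ccr2 and Retnlg also ended with the GC offsets, at 3.46 and 9.05 (edgeR adjusted p = 0.109 and 0.0614).

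Of 18 glycolysis genes 5 were lower in GF than in SPF mice at day 7, and 7 over the list alone, and of 17 immediate early genes 5, and 7 (limma camera adjusted p = 0.0193 and 0.0115, and adjusted p = 0.324 and 0.413 with an estimated correlation). Both calls ended with the GC offsets (limma camera adjusted p = 0.927 and 0.218), the first also without SPF ICH day 7 replicate 1 (0.111) and the second without GF ICH day 7 replicate 2 (0.0742). In edgeR 189 genes were higher and 2074 lower, with 5770 at unadjusted p below 0.05, against 6307 in DESeq2 and 3381 in limma voom. Abundant genes went the other way, with 166 higher and 103 lower, against 23 and 1971 among the rest. With the GC offsets 28 of those 166 and 54 of those 103 stayed called, so the abundant calls kept lean lower. The offsets correct too far here. Median GC content was 42.5% in higher, 51.2% in lower and 48.7% in other genes. The Spearman correlation with GC was −0.637 over 1563 abundant genes, and 605 lower genes had 0 counts in all 3 GF libraries. With the GC offsets, which turn that correlation to 0.292, 1491 of the 2263 calls were kept. The count was 1111 without GF ICH day 7 replicate 3 and 1438 without replicate 1. The median log2 fold change was −1.56, and −1.75 with DESeq2 size factors, and limma voom did not call Apoe or Cx3cr1 (limma adjusted p = 0.0822 and 0.0591).

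Does the response to ICH itself depend on the microbiota? Tests of the interaction at day 3 called 0 genes for ABX and 0 for GF mice in edgeR, with 980 and 999 at unadjusted p below 0.05, 670 and 495 calls in DESeq2 and 22 and 0 in limma voom. The Apoe response of GF mice differed from that of SPF mice by −3.23 ± 0.67 without passing in edgeR (adjusted p = 0.841), and passed in DESeq2 (−3.60, adjusted p = 0.0146). Cell cycle genes had an interaction median of −2.51 in GF mice at day 3, with 0 of 22 passing (limma camera adjusted p = 2.98e-08, and adjusted p = 0.171 with an estimated correlation). At day 7 0 genes passed for ABX mice in edgeR, with 2236 at unadjusted p below 0.05, 1935 in DESeq2 and 12 in limma voom. P2ry12 stood at 1.10 ± 0.50 (edgeR adjusted p = 0.374).

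For GF mice at day 7 the Apoe response differed from that of SPF mice by −6.16 ± 0.71 log2 units (edgeR adjusted p = 6.52e-05), and the Cx3cr1 response differed by −3.24 ± 0.64 and that of Csf1r by −5.59 ± 1.22 (edgeR adjusted p = 0.00487 and 0.00927). Between GF and SPF mice Apoe differed by 3.41 in sham and −2.76 at day 7, which together make up its difference in response. The Gpr34 response differed by 2.51 ± 0.47 (edgeR adjusted p = 0.00373). With the GC offsets, which turn the Spearman correlation with GC from −0.62 to 0.239, the Apoe difference was −3.46 (edgeR adjusted p = 0.00194) and calls of Gpr34 and Csf1r ended (edgeR adjusted p = 0.587 and 0.0976). Limma voom ended those of Apoe, Cx3cr1 and Csf1r (limma adjusted p = 0.304, 0.116 and 0.128). Glycolysis had 4 of 18 lower and 8 over the list alone, immediate early genes 4 of 17 and 8 (limma camera adjusted p = 0.00152 and 0.00326, and adjusted p = 0.0755 and 0.229 with an estimated correlation, and 0.364 and 0.239 with the GC offsets). In edgeR 50 genes were higher and 1188 lower, with 4424 at unadjusted p below 0.05, against 4931 in DESeq2 and 934 in limma voom. Among abundant genes 45 were higher and 111 lower, and among the rest 5 and 1077. The count was 247, 415 or 477 without SPF sham replicate 3, 2 or 1, 745 without SPF ICH day 7 replicate 2 or 3, 788 without GF ICH day 7 replicate 3, 769 with a replicate block and 627 with the GC offsets.

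Further marker lists passed in limma camera with no call under an estimated correlation (lowest limma camera adjusted p = 0.132). T and NK cell markers had medians of −1.86 at day 7 in SPF mice, 1.25 at day 7 in ABX mice, and −1.65 and 1.83 from day 3 to day 7 in SPF and ABX mice (limma camera adjusted p = 4.6e-05, 0.0257, 1.35e-05 and 0.0199). Their interaction medians at day 7 were 3.07 in ABX and 1.95 in GF mice (limma camera adjusted p = 5.48e-05 and 0.0123). Erythroid markers passed upward at day 7 in SPF and ABX mice, from day 3 to day 7 in ABX mice and in GF over SPF mice at day 3 (limma camera adjusted p = 0.0298, 0.0211, 0.0199 and 0.00569). Neutrophil medians were −4.04 at day 3 in ABX mice, 3.18 and 3.86 from day 3 to day 7 in ABX and GF mice, and 6.32 and 7.82 in the GF interactions at day 3 and day 7 (limma camera adjusted p = 0.0207, 0.0422, 0.0318, 0.02 and 0.00326). Monocyte medians were 2.46 from day 3 to day 7 in GF mice and 4.32 in the GF interaction at day 7 (limma camera adjusted p = 0.0248 and 0.026). Oligodendrocyte markers had −2.38 at day 7 in SPF mice, and border-associated macrophage and neuron markers −2.01 and 7.71 in the GF interaction at day 3 (limma camera adjusted p = 0.00422, 0.02 and 0.00206).

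Genes of short-chain fatty acid sensing and use were followed as a list of 19, of which 15 were measured. At day 3 in SPF mice the median was 0.41 with 0 of 15 passing (limma camera adjusted p = 0.0444, and adjusted p = 0.21 with an estimated correlation), a call that ended without SPF sham replicate 3 (limma camera adjusted p = 0.313). Medians were 0.17 at day 7 in SPF, −0.38 and −2.10 at days 3 and 7 in ABX and 0.16 at day 3 in GF mice, with 0 of 15 passing each time (limma camera adjusted p = 0.213, 0.923, 0.545 and 0.313). At day 7 in GF mice 4 of 15 fell, and 1 rose and 6 fell over the list alone, with a median of −5.06 (limma camera adjusted p = 0.555). They include the lactate transporter gene Slc16a3 at −9.77 and the acetyl-CoA synthetase gene Acss2 at −11.45 (edgeR adjusted p = 0.00419 and 0.0219), the second at 0.145 in edgeR without GF sham replicate 1 and both not called in limma voom (limma adjusted p = 0.266 and 0.193). Hcar2, a receptor for butyrate and ketone bodies, stood at 4.81 ± 1.71 at day 3 in SPF mice and 4.97 ± 1.72 at day 7 in GF mice and did not pass (edgeR adjusted p = 0.659 and 0.0533). The latter was 5.87 with the GC offsets and passed (edgeR adjusted p = 0.0385). Counts of the propionate receptor gene Ffar3 were 0 in all libraries, and Ffar2 had 678 counts in 2 libraries.

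The p-values of single genes above measure spread between libraries, which may be technical as well as between mice, and the at-least fold values cover counting error alone. Those of limma camera compare a list with all other genes, so at the preset correlation they do not measure that spread. The labels do not say whether each library comes from 1 mouse. Ftl1 and Lilrb4a share sequence with related genes, so their levels may include reads from those. On the mm10 assembly, Apoe lies at chromosome 7 19696109–19699188, Spp1 at chromosome 5 104435118–104441050, P2ry12 at chromosome 3 59216272–59262871, Cst3 at chromosome 2 148871722–148875692, Gpr34 at chromosome X 13632089–13640858, Csf1r at chromosome 18 61100598–61132149 and Cx3cr1 at chromosome 9 119901616–120069879.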

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

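The response to ICH at day 7 was compared between GF and SPF mice by an interaction test, and the difference between these groups brought 1 count and 18 genes forward. The tests on GC content, astrocytes and libraries with few detected genes below were chosen after the results were seen. Those on loss of transcripts, neutrophils and a single library were set before they were run, for patterns already found.

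The interaction passed for 1238 genes in edgeR. The GF response minus the SPF response, in log2 units, was above 0 for Gpr34 (2.51), P2ry12 (1.83) and B2m (1.31). It was below 0 for Cd68 (−1.52), C1qc (−2.37), C1qa (−2.42), Ctsb (−2.56), C1qb (−2.63), Eno1 (−2.73), Ftl1 (−3.07), Sparc (−3.11), H2-D1 (−3.16) and Cx3cr1 (−3.24). Ctsd (−3.43), Aldoa (−4.29), Csf1r (−5.59), Apoe (−6.16) and Dusp1 (−6.87) lay furthest below 0 among these 18, and a value below 0 can be a deeper fall in GF mice, as for Cx3cr1 and Csf1r, or lie in part between the shams, as for Apoe, which is 3.41 higher in GF than in SPF sham. With the GC offsets, which correct too far in this comparison, Ctsb, Cx3cr1 and Apoe kept their calls and the other 15 did not, among them Eno1, Ftl1, Sparc, H2-D1, Ctsd, Aldoa and Dusp1 (edgeR adjusted p = 0.971, 0.696, 0.109, 0.657, 0.317, 0.349 and 0.0711). Of 25 random divisions of these libraries, 2 gave as many genes, the real one and another with 1523, so chance cannot be excluded as the source of the count. ICH and sham libraries were divided apart, so a division can keep the real ICH groups. Whether the one with 1523 does was not recorded.

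Among abundant genes lower in GF than in SPF mice at day 7, 54 of 103 stayed lower with the GC offsets, which turn the correlation with GC from −0.637 to 0.292 and so correct too far, and a part for GC content stays open. Among less abundant lower genes 1402 of 1971 stayed lower, and 942 of the 1366 with counts in GF ICH day 7. The offsets took the correlation over less abundant genes from −0.224 to −0.0116. The median log2 fold change of the 1971 went only from −8.15 to −7.86. The offsets were fitted on abundant genes and cannot undo a loss of nearly all counts. Most of these calls could thus stay in any case, and the part of GC content stays open. Loss of transcripts from libraries with few detected genes would also empty the same genes in GF sham replicates 1 and 2, and the excess at 0 counts there over expression-matched genes was 0.480 points (18.9 against 18.4%). In GF sham replicate 3 the matched genes were at 0 in 0.238%, so they lose counts in replicates 1 and 2 as well, the bound set before decides nothing and loss stays open. Whether the germ-free state itself lowers these genes was not tested, since the 3 GF libraries of that day are also among the 7 under 12000 detected genes.

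Neutrophil markers higher in GF than in SPF mice at day 3 were weighed against neutrophils among the sorted cells and a single library. Of a further 31 neutrophil genes, none on the first list, 23 were measured, with a median log2 fold change of 0.90 and 18 above 0, higher than 99.1% of expression-matched lists. This goes with neutrophil RNA in the sort, although no gene passed alone, and the most abundant ones, Ifitm2 and Ifitm1, stood at 296 against 172 and 139 against 31.2 CPM and are expressed by microglia too. The largest rises, Trem1, Cd177 and Wfdc21, stood at 5.67, 1.29 and 0.410 CPM against 0. The genes not above 0 were Lrg1, Hdc, Lcn2, Fpr2 and Clec4e. The random lists draw genes independently, so the percentile ignores correlation among neutrophil genes. At the preset correlation the call did not rest on a single library, since the camera adjusted p in limma stayed at 5.39e-05 or below whichever of the 6 was left out. That p-value does not measure spread between libraries. Leaving out libraries was not repeated with an estimated correlation, where limma camera gave adjusted p = 0.0155 with all of them. A sort for microglia would remove neutrophils, but the labels give no gate. Whether GF mice hold more of them around the hematoma was not tested.

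Apoe higher in GF than in SPF sham was weighed against GC content, astrocyte RNA and the GF sham libraries with few detected genes. With the GC offsets the fold change went from 3.41 ± 0.51 to 2.11 ± 0.39 and the call ended in edgeR (adjusted p = 0.262), which leaves a part for GC content open. Without the 7 libraries under 12000 detected genes it was 2.72 ± 0.50 and did not pass in edgeR (adjusted p = 0.137), with 1 GF sham library left, which also stays open. A rise in RNA from astrocytes, which express Apoe, is argued against by summed levels of their marker list, 277 ± 115 against 468 ± 221 CPM. That the list was lower is not shown, since its median of −6.03 did not pass (limma camera adjusted p = 0.0688, and adjusted p = 0.239 with an estimated correlation). GF sham replicates 1 and 2, with few detected genes, also enter these values. An effect of the germ-free state on Apoe may remain and was not separated from these.

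Divisions of the 6 libraries into groups of 3 number 10 with the real one, too few for a share under 0.05. The other divisions mix libraries of the 2 groups, so a real difference adds to the spread within them. A low count in them is thus likely from the start and is no separate evidence. The real division gave the most genes, and any other 0, for ICH day 3 in SPF (18), ABX (22) and GF mice (1), ICH day 7 in SPF (14) and ABX mice (166), day 7 against day 3 in GF mice (2680), GF against SPF sham (1), ABX against SPF at day 7 (15) and GF against SPF at day 7 (2263). In these, 1 of 10 divisions reached the count. For day 7 against sham in GF mice 1 of 10 reached 2536, with 1420 in the next, and for day 7 against day 3 in ABX mice 1 of 10 reached 128, with 1 in the next. All 10 of 10 gave 0 genes for day 7 against day 3 in SPF mice, ABX against SPF sham, and ABX or GF against SPF at day 3. All 25 of 25 gave 0 for the interactions of ABX at day 3 and day 7 and of GF at day 3.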

How the results depend on the processing

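Without the 7 libraries, with genes of at least 100 mean CPM alone, and with GC offsets are alternatives chosen after seeing the data, and the others were set before. Counts of genes that differ by more than 1.5 times are given by comparison, and the cause was not tested except where fewer genes or libraries enter. Responses are called by condition and day against sham. Of the results for named genes, DESeq2 kept 442, weakened 4 and strengthened 19, voom kept 334 and weakened 126, size factors kept 432 and weakened 36, no filter kept 416 and weakened 53, the replicate block kept 426 and weakened 42, and the GC offsets kept 333, weakened 112 and reversed 22. Leaving out 1 library kept 2706, weakened 604 and reversed 2. Of list results, an estimated correlation kept 365 and weakened 110. In these tallies kept also covers results that passed in neither setting, so it does not count calls that held. Weakened counts calls that were lost. At equal depth detected genes still ran from 9061 to 18066, and the effect of depth on the counts of calls was not tested.

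DESeq2 called 954 genes for SPF day 3, 709 for SPF day 7, 1086 for ABX day 3, 4890 for ABX day 7, 720 for GF day 3 and 6932 for GF day 7. From day 3 to day 7 it called 662 in SPF, 4817 in ABX and 6852 in GF mice. Over SPF it called 576 in ABX and 876 in GF sham, 761 and 571 at day 3, and 4466 and 6307 at day 7. For interactions it called 670 (ABX) and 495 (GF) at day 3, and 1935 and 4931 at day 7.

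Voom called 529 for SPF day 3, 148 for SPF day 7, 868 for ABX day 3, 581 for ABX day 7, 0 for GF day 3 and 1197 for GF day 7. From day 3 to day 7 it called 88 in SPF, 349 in ABX and 5014 in GF mice. Over SPF it called 108 in ABX and 0 in GF sham, 38 and 260 at day 3, and 258 in ABX at day 7. For ABX interactions it called 22 at day 3 and 12 at day 7.

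Size factors gave 9 for SPF day 3, 14 for ABX day 3, 90 for ABX day 7, 64 for ABX from day 3 to day 7, 0 for GF over SPF sham and 0 for ABX over SPF at day 7. No filter on low counts gave 56 for ABX day 7, 31 for ABX from day 3 to day 7 and 0 for ABX over SPF at day 7. The replicate block gave 105 for ABX day 7, 0 for ABX over SPF at day 7 and 769 for the GF interaction at day 7.

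Without the 7 libraries under 12000 detected genes there were 297 for SPF day 3, 74 for SPF day 7, 290 for ABX day 3, 2145 for ABX day 7, 2 for SPF from day 3 to day 7, 2145 for ABX from day 3 to day 7, 0 for GF over SPF sham, 1896 for ABX over SPF at day 7 and 827 for the ABX interaction at day 7. That leaves 1 library in ABX ICH day 7 and 1 in GF sham, each taken to vary like the other groups, and gives no value for GF ICH day 7. Genes of at least 100 mean CPM gave 71 for SPF day 3, 31 for SPF day 7, 77 for ABX day 3, 24 for GF day 3, 467 for GF day 7, 455 for GF from day 3 to day 7, 52 for ABX and 317 for GF over SPF at day 7 and 202 for the GF interaction at day 7, with fewer genes tested. GC offsets gave 2 for GF day 3, 1757 for GF from day 3 to day 7, 0 for GF over SPF sham, 1 for ABX over SPF at day 7 and 627 for the GF interaction at day 7.

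With 1 library left out, the lowest and highest counts were 7 and 13 for SPF day 3, 5 and 16 for SPF day 7, 7 and 20 for ABX day 3, 29 and 603 for ABX day 7, 1 and 54 for GF day 3, and 1648 and 2722 for GF day 7. They were 29 and 637 for ABX and 1594 and 2477 for GF from day 3 to day 7, 0 and 35 for GF over SPF sham, and 0 and 388 for ABX and 1111 and 2180 for GF over SPF at day 7. For interactions they were 0 and 16 (GF day 3), 0 and 4 (ABX day 7) and 247 and 1610 (GF day 7).

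Log2 fold changes of these genes reversed with the GC offsets, which correct too far in all comparisons with GF ICH day 7. For GF day 7 they became 2.41 (Apoe, which then passed), 0.40 (Eno1), 0.18 (C1qc), 0.13 (C1qb) and 0.13 (C1qa). For GF from day 3 to day 7 they became −0.15 (P2ry12), −0.24 (Cox7c), 1.40 (Apoe), 0.79 (H2-K1), 0.27 (C1qa), 0.37 (C1qb) and 0.17 (Tmem119). For GF over SPF at day 7 they became −0.34 (P2ry12), −0.14 (B2m) and 0.31 (C1qb), and for the GF interaction −0.10 (P2ry12), −0.42 (B2m), 0.20 (Cd68), 0.15 (H2-K1), 0.30 (C1qc), 0.32 (C1qa) and 0.083 (C1qb). For GF day 7, Ch25h ran from −0.33 without GF ICH day 7 replicate 3 to 7.14 without GF sham replicate 1, and Mcm5 from −11.77 to 0, the latter without GF sham replicate 3. Lists that reversed are given with limma camera adjusted p. Immediate early genes ran from 0.000196 to 0.787 for SPF day 3 and from 0.000238 to 0.373 for SPF day 7, with the direction reversed without SPF sham replicate 2, and had 0.365 for GF day 3 and 0.00398 for the GF interaction at day 3 without the 7 libraries. Homeostatic genes had 0.00147 for the latter interaction without the 7 libraries, and complement genes 0.00592 for GF day 7 with the GC offsets. The cause was not tested.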

Other observations

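Among genes higher at day 7, ABX and GF mice shared 77, where 2.19 would be shared by chance, and SPF and ABX mice shared 14, where 0.103 would be. The 77 include mt-Co1, mt-Cytb and mt-Nd4 of the mitochondrial genome, which stand beside the higher mitochondrial share of those libraries, and Gpnmb, Lgals3 and Lamp2, all named after the values were seen and with no test of enrichment. Lower genes shared by ABX and GF mice numbered 25, against 4.71 by chance, among them Glb1 and Icam1. GF mice share no sham libraries with ABX mice. The chance value takes the calls as independent draws, but both comparisons share a GC trend (Spearman −0.272 in ABX and −0.546 in GF mice) and libraries with few detected genes, so a larger overlap may arise from these.

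Correlations between replicates of a group were lowest in GF sham (0.626 to 0.708) and GF ICH day 7 (0.657 to 0.682) and highest in GF ICH day 3 (0.828 to 0.874). The first principal component held 36.8% and the second 7.80% of variance. The first ran from 54.6 to 197 in the 7 libraries under 12000 detected genes and from −102 to 17.5 in the other 20. Among those 20 it fell as detected genes rose (Pearson −0.806). Among the 7 the Pearson correlation was −0.851, and −0.581 without the 2 farthest libraries. Detected genes also differ by group, so the 2 are not told apart here. The most counted 50 genes took 28.8 to 41.3% of a library. Ly6g, a granulocyte surface marker, had 2186 counts in 2 libraries, and Ptgs2 had 95 in 3.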
